A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

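RNA abundance was measured by sequencing total RNA of the fission yeast Schizosaccharomyces pombe. The labels name 4 libraries, 2 of a strain labelled as a loz1 deletion and 2 of wild type. Per the labels' protocols, both strains grew in a zinc-limited minimal medium with zinc added back, to an OD600 of about 6.0, and the labels give the added zinc as 100 mM. That unit is copied from the labels and was not checked. Per the labels' protocols, a sequencing company prepared the libraries with standard Illumina methods, so no strand-marking kit is named. Nothing in the labels says that libraries of one group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

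The deposited files hold 1 annotated transcript per line with an FPKM value, the number of fragments scaled to transcript length and to the sequenced total, and a lower and upper bound of that value, made by Cufflinks per the file headers and attribute names. The score column that the authors deposited beside it, relative to the main transcript of a locus, was not used. Per the submitters' processing notes, HISAT2, SAMtools, Cufflinks and Cuffdiff were run on the genome build ASM294v2, and versions, the strand setting, the treatment of reads with several matches and any masking are not given in the sources used here. Each file lists the same 7093 transcripts of 7092 genes, and replicates were not pooled. FPKM values cannot be used as counts, and without a stated strand setting the reads of a gene and of an antisense partner cannot be told apart. Coordinates are those of the files. The reference annotation at hand is RefSeq's for the species, in a later release of the assembly. Of 5326 introns in the files 98.0% were identical in it, and 99.7% of 5301 introns began and ended with the usual splice bases in its sequence, so it was used for gene names and sequence context on chromosomes I, II and III. In all, 6742 gene identifiers matched it, and 5105 genes were protein coding.

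The files give no read totals. Cufflinks' bounds narrow with the fragments behind a value, and from them the depth was estimated at 1.80e+07 and 1.94e+07 fragments for the labelled deletion libraries, replicates 1 and 2, and at 1.71e+07 for each wild-type library. These are estimates, and the precision they give covers counting error only. Summed FPKM was 1.05e+06, 1.02e+06, 1.19e+06 and 1.32e+06 in the same order.

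FPKM was summed over the transcripts of a gene. Genes with a mean of at least 1 FPKM over the 4 libraries and a longest transcript of at least 200 nt were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using an empirical Bayes prior with an intensity trend and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Every adjusted p given for a gene is from this limma model, with n = 2 per group, and every fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. Values were compared as deposited, without rescaling. The test, the filters, the 25 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested as sets with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists. Its direction is relative to all other tested genes. A second count was adjusted over the list alone.

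The rule for named genes took loz1, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 FPKM and non-overlapping groups, the 5 largest rises and 5 largest falls of other genes by the same criteria, all tested members of both zinc lists, up to 4 members of every other list with the smallest p, and tested partners that overlap at least 20% of the transcript of loz1, of the largest rises and falls or of a zinc list member. Other called list members were named after their values were seen. Overlap with other annotated transcripts was measured along each transcript, and sequence sharing as the percent of transcript positions at which a 100-nt stretch starts that occurs more than once in the reference. The lists were written from knowledge of the genes, with no literature at hand, and members without a match in the files were left out. What genes encode is as the RefSeq annotation names it or general background.

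The model was tested on simulated libraries of the 6315 genes tested, drawn at the estimated depths. All genes of a group were given a common spread, taken from its replicate pair. Changed genes were drawn among those of at least 5 FPKM. The model recovered 16.0% of 50 genes changed 1.5-fold and 80.0% of 50 changed 2-fold. It recovered all 50 genes of each of the 4-fold and 8-fold sets. Of 6115 unchanged genes 2 were called. Differences in spread between genes were not simulated, so these rates may not hold for the real libraries.

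The alternatives were other pseudocounts (0.1 and 5), filters and priors, median-ratio rescaling, quantile normalization, protein-coding genes only, the most abundant transcript of each gene, the replicate number as a block, a fold rule without a test, and leaving out each library in turn, where the lone library is assumed to vary like the other group. Added after the data were seen were limma's voom on estimated fragments, fits without genes that share at least 10% of their sequence or overlap others over at least 10% of their length, the set test with quantile normalization, and counts of the motif, of genes near chromosome ends and around adh4 from the other calls. Shares of RNA classes were compared with an exact permutation test, which cannot go below p = 0.333 with 2 against 2. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes on the mitochondrial, mating-type and unplaced sequences were left out of the sequence-context counts.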

Results

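Gene expression was measured by RNA sequencing in fission yeast of 2 genotypes given zinc, to ask which genes depend on Loz1, a zinc finger protein that represses genes when zinc is plentiful. There were 2 libraries of the strain labelled as a loz1 deletion and 2 of wild type. The depth estimated from the bounds of the deposited values was 1.80e+07 and 1.94e+07 fragments for the labelled deletion libraries and 1.71e+07 for each wild-type library. Pearson's r across genes, which are not independent replicates, was 0.991 between the labelled deletion libraries and 0.968 between the wild-type libraries, and 0.911 to 0.925 between groups. The wild-type pair differed more, by a median of 0.24 on the log2 scale against 0.09.

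The targeted gene itself went against the label. The loz1 transcript (SPAC25B8.19c, chromosome I, 4192070 to 4195228, minus strand, 1 exon) was listed at 56.4 and 56.0 FPKM in the libraries labelled loz1 deletion and at 6.87 and 5.81 FPKM in wild type, a rise of 2.97 ± 0.14 (log2, SE, adjusted p = 0.00112). The annotated coding sequence lies at 4192642 to 4194210 in the RefSeq annotation, so 50.3% of the 3159-nt transcript lies outside it. The labels do not describe the deleted part, and the files give 1 value for the whole transcript, so reads inside and outside the coding sequence cannot be separated. All directions are therefore given for the libraries as labelled.

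Among 6315 genes tested, 753 were higher and 276 lower in the labelled deletion libraries than in wild type. The rises included zrt1 and adh4, and the falls included the metallothionein gene zym1 and pheromone genes. Of these calls 269 and 150 were at least 2-fold, and 99 and 57 at least 4-fold. Higher genes comprised 655 protein-coding and 90 non-coding RNA genes, lower genes 172 and 97. Groups did not overlap in 44.7% of tested genes in the higher direction and in 21.7% in the lower, where chance gives 16.7% each. The median of all tested genes lay at 0.13 (log2), a shift that every fold change given here includes. Median-ratio rescaling, which moves the median by 0.13, gave 428 higher and 323 lower genes, so that higher genes made up 57.0% of the calls in place of 73.2%. All 428 were among the 753, and 259 of the 323 were among the 276. When labelled deletion replicate 1 or 2 was left out the counts were 80 higher and 40 lower or 73 higher and 40 lower, and when wild-type replicate 1 or 2 was left out they were 2115 and 880 or 1593 and 793. Each of the 753 and 276 genes kept its direction in these 4 fits. Leaving out a library cannot reverse a gene whose groups do not overlap, so this gives no separate support. Such a fit takes its spread mainly from the pair left whole, and the wild-type pair differed more (a median of 0.24 against 0.09, log2). Calls lost without a labelled deletion library, or kept without a wild-type library, may therefore reflect that spread and not the library left out. This holds for all such calls given below.

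**Figure D1:**
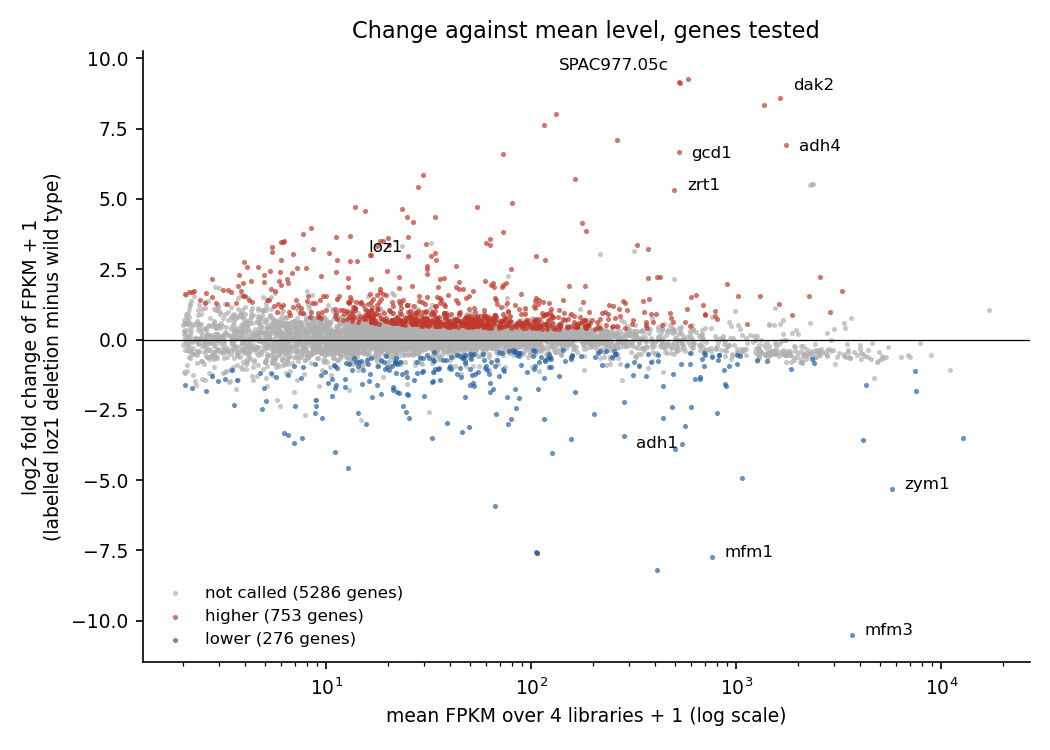
Log2 fold change of FPKM + 1 (labelled loz1 deletion minus wild type, vertical axis) against the mean FPKM + 1 of the 4 libraries on a log axis, 1 point per tested gene, with 753 genes called higher in red, 276 called lower in blue and the rest in grey. The named rises adh4 and dak2 lie at 6.92 and 8.58, the named falls zym1 and mfm3 at -5.33 and -10.50.

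Zinc genes changed in both directions. The plasma membrane zinc importer gene zrt1 (SPBC16D10.06, II, 3607199 to 3609330) was at 971 ± 9.47 FPKM in the labelled deletion libraries and at 24.4 ± 9.37 FPKM in wild type (mean ± SD, n = 2), a rise of 5.31 ± 0.26 (log2, SE, adjusted p = 0.00127). The metallothionein gene zym1 (SPAC22H10.13, I, 2381690 to 2382200) fell by 5.33 ± 0.14, from 11171 ± 477 to 277 ± 14.9 FPKM (adjusted p = 0.000226). Of the 7 genes of zinc transport and storage, 3 rose (zrt1, loz1 and the Golgi zinc importer gene zrg17) and 1 fell, and adjusted over the list alone 4 rose and 1 fell. The remaining members were fet4 at 9.54 ± 0.802 against 5.44 ± 1.69 FPKM, zhf1 at 249 ± 15.4 against 174 ± 48.6 FPKM, and cis4 at 22.3 ± 3.56 against 19.4 ± 2.09 FPKM, which were not called over all genes. The call of zrg17 (1.42 ± 0.27, adjusted p = 0.0319) was lost after rescaling and when either labelled deletion library was left out. As a set the list did not pass (camera, adjusted p = 0.18).

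The zinc-responsive genes of earlier Loz1 work all changed, 6 higher and 1 lower of 7 tested, with the same counts adjusted over the list alone. The 6 include the targeted gene loz1 itself. They also include SPAC977.05c and SPBC1348.06c, which share sequence with other loci and may not be separate measurements. Beside zrt1 and loz1, the alcohol dehydrogenase gene adh4 (SPAC5H10.06c, I, 156430 to 158307) was at 3461 ± 199.8 against 28.1 ± 6.77 FPKM, a rise of 6.92 ± 0.18 (adjusted p = 0.000226). The gene gcd1, annotated as a glucose-6-phosphate 1-dehydrogenase, was at 951 and 1122 FPKM against 20.7 and 3.76 FPKM, a rise of 6.67 ± 0.70 (adjusted p = 0.00784). SPAC977.05c and SPBC1348.06c rose by 9.28 and 9.16, to 1153 ± 49.3 and 1047 ± 53.8 FPKM, but 73.3% and 100% of their sequence occurs at other loci too, so their reads cannot be assigned to 1 copy. As a set the list was higher (camera, adjusted p = 0.000777), with an adjusted p = 0.556 with an estimated correlation. All 7 calls were kept whichever library was left out and after rescaling.

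The alcohol dehydrogenase gene adh1 (SPCC13B11.01, III, 1589427 to 1592889) was the member that fell, by 3.42 ± 0.43 (adjusted p = 0.0123). It was at 386 and 642 FPKM in wild type and at 30.6 and 67.6 FPKM in the labelled deletion libraries. On the opposite strand SPCC13B11.02c (III, 1589996 to 1593818) rose by 8.33 ± 0.64, from 3.23 and 15.9 FPKM to 2676 and 2767 FPKM (adjusted p = 0.00349). Other transcripts cover 93.2% of adh1 and 100% of SPCC13B11.02c, so with an unstated strand setting the values of this pair are uncertain. SPNCRNA.2001, which overlaps both, rose by 3.76 ± 0.40. SPNCRNA.2002, which overlaps both too, was not called, and its change ran from -0.37 to 2.59 with a library left out.

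In the list of alcohol dehydrogenases and abundant zinc enzymes, 3 of 10 tested genes rose and 1 fell (4 and 2 adjusted over the list alone). The called genes were adh4, adh1, the alkaline phosphatase gene pho8 (1.31 ± 0.18, adjusted p = 0.0143) and the isopropylmalate synthase gene leu3 (0.61 ± 0.11, adjusted p = 0.0266), whose call was lost after rescaling. The fructose-bisphosphate aldolase gene fba1 was at 2876 ± 346 against 2918 ± 561 FPKM and was not called (adjusted p = 0.97). As a set the list did not pass (camera, adjusted p = 0.978). When either labelled deletion library was left out the calls of pho8 and leu3 were lost, while adh4 and adh1 stayed called.

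**Figure D2:**
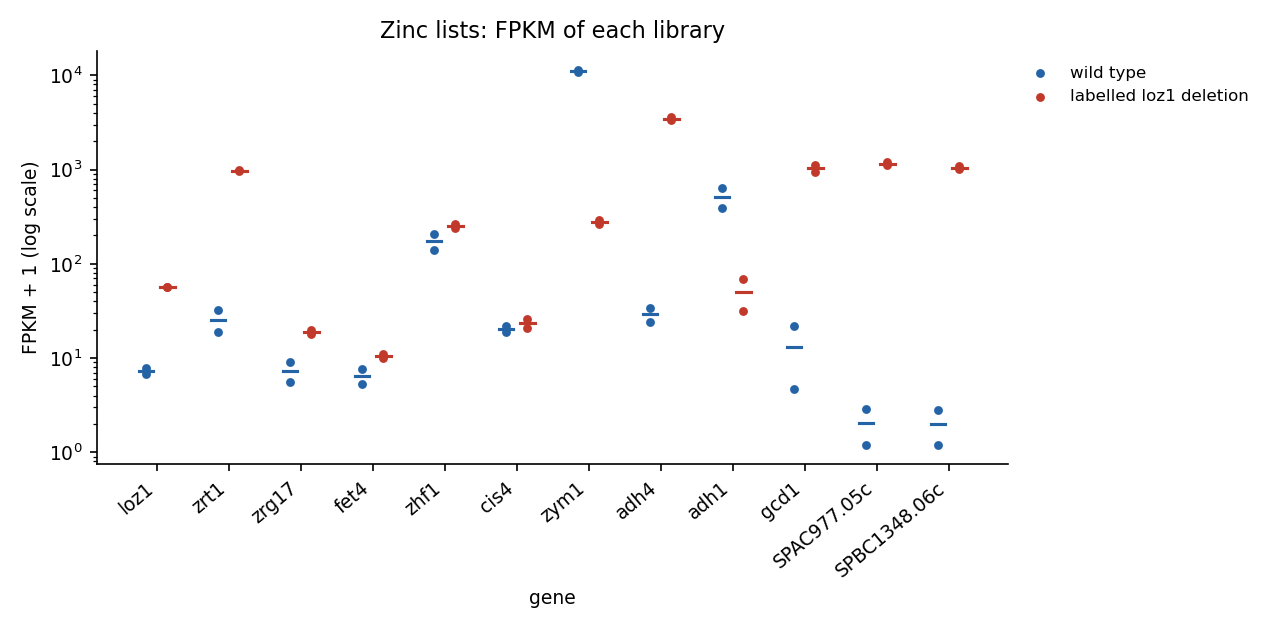
FPKM + 1 on a log axis of the genes of both zinc lists in each library, wild type in blue and labelled loz1 deletion in red, with points for the 2 libraries of a group and a bar at their mean. For zrt1, adh4 and gcd1 the lowest labelled deletion library lies at 951 FPKM and the highest wild-type library at 32.8 FPKM, while zym1 and adh1 lie the other way round.

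The remaining large changes among protein-coding genes included a dihydroxyacetone kinase gene and pheromone precursors. The gene dak2 (SPAC977.16c, I, 64559 to 66980) was at 3268 ± 161 against 7.62 ± 1.54 FPKM, a rise of 8.58 ± 0.15 (adjusted p = 0.000101), and SPAC977.17 of the MIP channel superfamily, which it overlaps, rose by 7.11. SPBPB2B2.15, of which 87.9% is sequence found elsewhere too, rose by 9.11, SPAC4H3.17 by 5.85, SPAC22H10.06c by 5.72 and SPAPJ695.02 by 5.43. SPAC4H3.17 is fully overlapped by SPAC4H3.01, which rose by 1.49, and SPAC22H10.06c ends at 2381601 on chromosome I, next to zym1 and on the other strand. The falls included SPAC513.04 (-8.22), the flavin oxidoreductase gene SPBC23G7.10c (-5.93), SPBPB21E7.10 (-4.04), the hexose transporter gene ght7 (-3.99), cum1 (-3.56) and min8 (-3.56). Transcripts of other genes cover 100% of cum1, 75.2% of SPBPB21E7.10 and 69.5% of min8. Of their partners, SPBPB21E7.11 fell by 2.40, while iss1, which overlaps cum1, was at 75.8 ± 3.40 against 75.3 ± 2.56 FPKM and was not called. All 12 named rises and 11 of the 12 named falls stayed called whichever library was left out. The exception was ght7, at 6.93 and 32.9 FPKM in wild type, which lost its call when either labelled deletion library was left out.

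Among genes not classed as protein coding, SPNCRNA.1317 was at 260.5 ± 20.9 FPKM in the labelled deletion libraries. In wild type it was at 5.5e-10 FPKM on average. It is fully overlapped by the maltase gene mal1, which rose by 1.11. SPNCRNA.425, which lies before zrt1 (II, 3605142 to 3606517), rose by 6.59, and SPNCRNA.1622 on its other strand by 2.41. SPNCRNA.136 rose by 4.56, and prl37 was at 14.8 ± 1.48 FPKM and listed at 0 in both wild-type libraries. Overlapping transcripts cover 84.7% of SPNCRNA.425 and 82.6% of SPNCRNA.136, and 85.6% of SPNCRNA.136 is sequence found elsewhere too. The falls were SPNCRNA.388 (-4.56), SPNCRNA.1320 (-3.91), SPNCRNA.31 (-3.73) and SPNCRNA.398 (-3.67), and SPMTR.04, which is given with the mating genes. The rise SPMTR.01 is given there too. SPMTR.01 and SPMTR.04 were unclassified, as the mating-type sequence is not in the reference, so they may be protein coding. Overlapping transcripts cover 97.6% of SPNCRNA.1320 and 100% of SPNCRNA.31 and SPNCRNA.398. The 5 named rises and 5 named falls of this kind stayed called whichever library was left out.

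Genes of mating and meiosis were lower as a group, with members of the 2 cell types moving apart. Of 22 tested members of the nitrogen starvation, mating and meiosis list, 10 fell and 2 rose (11 and 3 adjusted over the list alone). As a set the list was lower (camera, adjusted p = 4.72e-05), with an adjusted p = 0.556 with an estimated correlation. The M-factor pheromone genes mfm3, mfm1 and mfm2, made by M cells, changed by -10.50, -7.73 and -4.93. In FPKM mfm3, which other transcripts cover completely and whose call was lost with voom, was at 2104 and 12588 in wild type and at 4.32 and 1.38 in the labelled deletion libraries. The M-factor exporter gene mam1 and the P-factor receptor gene mam2 changed by -3.02 and -1.86, the exchange factor gene ste6, also covered completely, by -2.99, and ste11, the transcription factor of the mating programme, by -1.16. The other falls were those of rgs1 (-1.77, 50.2% overlapped), the MAP kinase gene spk1 (-1.31, 71.2% overlapped) and the meiosis gene mei2 (-0.92). The P-factor gene map2, made by P cells, instead rose by 2.78 ± 0.19, from 2.56 ± 0.33 to 23.5 ± 3.53 FPKM (adjusted p = 0.00288). The M-factor receptor gene map3, 51.7% overlapped, rose by 0.95, a call lost after rescaling. When either labelled deletion library was left out, 5 of the falls and 1 of the rises stayed called.

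The mating-type cassettes differed between the groups. The M-specific genes mat1-Mc (II, 2114449 to 2115027) and mat3-Mc (II, 2132849 to 2133394), which share all of their sequence with other loci, were at 159 to 264 FPKM in wild type and at 0 to 0.15 FPKM in the labelled deletion libraries. SPMTR.04, on the separate mating-type sequence, was at 159 and 262 FPKM in wild type and at 0 and 0.15 FPKM in the labelled deletion libraries. Its length, 546 nt, is that of mat3-Mc and its values are nearly the same, so it may not be a separate signal. On the separate mating-type sequence SPMTR.01 was at 239 and 216 FPKM in the labelled deletion libraries and at 0 and 0.302 FPKM in wild type. SPBC23G7.10c and SPNCRNA.388, which fell, lie between mat1-Mc and mat3-Mc, at 2118146 to 2119536 and 2115592 to 2117167. Of 11 spore and late meiosis markers, dmc1, a recombination gene fully overlapped by other transcripts, was the 1 called (0.96, and 1 adjusted over the list alone), and its call was lost with quantile normalization and when either labelled deletion library was left out. That list had a mean of 0.13 and a median of 0.01, which turned to -0.11 after rescaling, and a set test pointing lower (camera, adjusted p = 0.978).

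**Figure D3:**
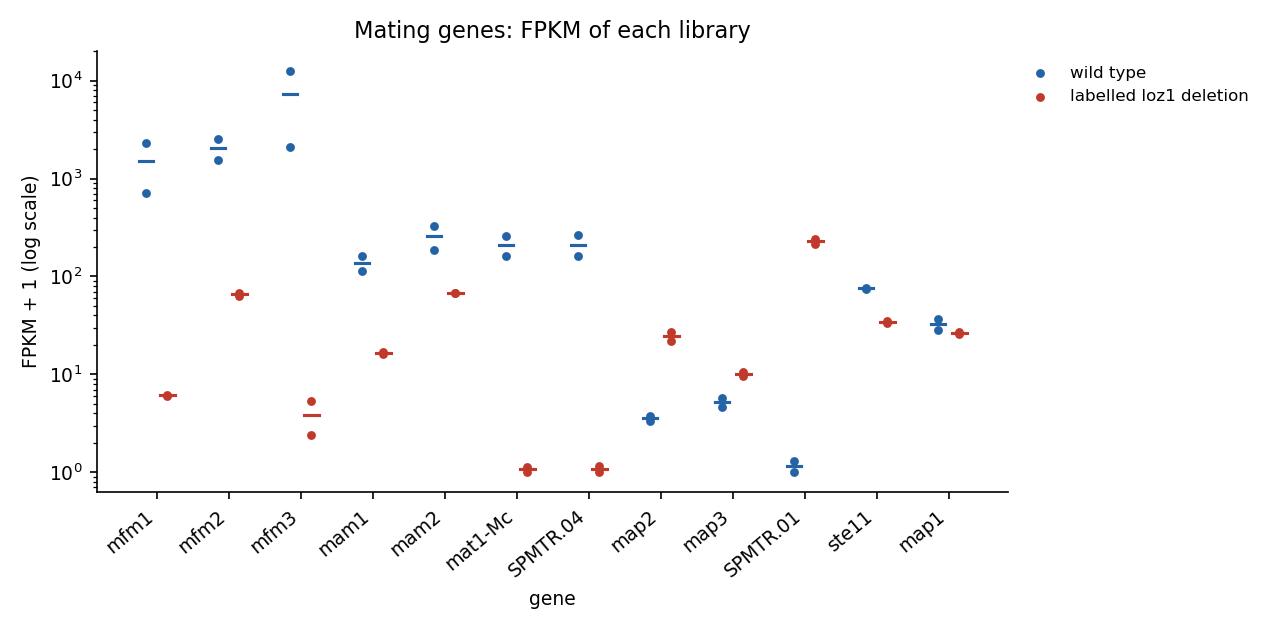
FPKM + 1 on a log axis of mating genes in each library, wild type in blue and labelled loz1 deletion in red, with points for the 2 libraries of a group and a bar at their mean. The M-cell genes from mfm1 to mam2, mat1-Mc and SPMTR.04 lie higher in wild type, while map2, map3 and SPMTR.01 lie higher in the labelled deletion libraries.

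Transcripts of some sugar metabolism genes were called, in both directions. In the list of hexose transport, gluconate and glucose-repressed genes 8 of 21 tested members rose and 2 fell (9 and 3 adjusted over the list alone). Besides dak2, the hexose transporter gene ght2 rose by 1.42 ± 0.12 (158 ± 15.7 against 58.4 ± 4.56 FPKM, adjusted p = 0.0042) and the dihydroxyacetone kinase gene dak1 by 1.54 ± 0.16. The hexose transporter genes ght1 and ght4, the latter 57.8% overlapped, rose by 4.13 and 1.92. The falls were ght7 and the alpha-glucosidase gene agl1 (-2.38). When labelled deletion replicate 1 or 2 was left out, 4 or 3 of the rises and neither fall stayed called. After rescaling 7 of the 8 rises and both falls were kept. Of 16 tested glycolysis genes 4 rose and 3 fell (6 and 3 adjusted over the list alone). The pyruvate decarboxylase gene pdc101 rose by 1.56 ± 0.13, the hexokinase genes hxk2 and hxk1 rose by 1.21 and 0.99, and the triosephosphate isomerase gene tpi1 by 0.96, a call lost after rescaling. The pyruvate decarboxylase genes pdc201 and pdc202 and the enolase gene eno102 changed by -1.66, -0.73 and -1.39. All 7 glycolysis calls were lost when either labelled deletion library was left out. Neither set passed (camera, adjusted p = 0.139 and 0.978), though the first passed after rescaling and both passed, as higher, with quantile normalization.

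Acid phosphatase genes rose. In the phosphate acquisition list 3 of 7 tested members were higher, with the same count adjusted over the list alone. The secreted acid phosphatase gene pho1 was at 592 ± 45.1 against 58.6 ± 19.0 FPKM, a rise of 3.35 ± 0.23 (adjusted p = 0.00288), the thiamine-repressible acid phosphatase gene pho4 rose by 2.52 ± 0.25, and the glycerophosphodiester transporter gene tgp1 by 2.32 ± 0.17. The phosphate transporter gene pho84 was at 237 ± 0.195 against 185 ± 44.2 FPKM and was not called. As a set the list did not pass (camera, adjusted p = 0.104), and when labelled deletion replicate 2 was left out the call of pho4 was lost.

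Among 7 thiamine genes 2 rose (3 adjusted over the list alone; camera, adjusted p = 0.252, though the set passed as higher with quantile normalization), the vitamin B6 importer gene bsu1 by 1.90 ± 0.24 and the thiamine synthesis gene thi4 by 0.99 ± 0.10. The call of bsu1 was lost when labelled deletion replicate 2 was left out, and that of thi4 when either labelled deletion library was. The thiamine-regulated gene nmt1, fully overlapped, was at 22864 ± 2334 against 11440.0 ± 3721 FPKM and was not called.

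Sterol genes were called higher more often than lower. Of 13 ergosterol genes and sterol regulator targets, 5 rose and 1 fell (6 and 1 adjusted over the list alone). The sterol desaturase gene erg31 was at 103 ± 7.80 against 25.2 ± 3.90 FPKM (adjusted p = 0.00298). The squalene monooxygenase gene erg1 rose by 1.74, erg25 by 1.04, erg11 by 1.39 and erg6, which is fully overlapped, by 1.93, and hem14, also fully overlapped, changed by -1.14. As a set the list did not pass (camera, adjusted p = 0.0564), though it did, as higher, after rescaling, with quantile normalization and with the replicate block. The calls of erg31 and erg1 were kept when labelled deletion replicate 1 was left out, and that of erg31 alone when replicate 2 was.

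In the cell wall and septum list 7 of 13 tested genes were higher (9 adjusted over the list alone), namely adg1 (2.80 ± 0.33), the glucan-modifying genes gas1 (1.57 ± 0.30) and gas2 (1.09 ± 0.13, 89.0% overlapped), adg2 (0.96), agn1 (0.85), mid2 (0.75, fully overlapped) and cfh4 (0.56). After rescaling 4 of the 7 calls were kept, without gas1, agn1 and cfh4, and all 7 were lost when either labelled deletion library was left out. The set was higher (camera, adjusted p = 0.0342), with an adjusted p = 0.556 with an estimated correlation. Of 11 amino acid and base synthesis genes used as strain markers 4 rose, his3 by 1.27 ± 0.09 (87.3% overlapped), arg3 by 1.20 ± 0.14, lys3 by 0.85 and ade6 by 0.49, and 9 rose adjusted over the list alone. The call of ade6 was lost after rescaling, and those of all 4 when either labelled deletion library was left out. This set was higher too (camera, adjusted p = 0.00791), again with an adjusted p = 0.556 with an estimated correlation. The uracil synthesis gene ura4, the member not tested, was listed at 0 in all 4 libraries.

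Stress and redox lists did not pass as sets. In the oxidative stress and thioredoxin list 5 of 17 tested members rose and 1 fell (6 and 2 adjusted over the list alone; camera, adjusted p = 0.522). The quinone dehydrogenase gene obr1, fully overlapped, rose by 1.97 ± 0.11, the sulfiredoxin gene srx1 by 1.87 ± 0.17, and the peroxiredoxin gene tpx1 by 1.71 ± 0.23, from 1554 ± 386 to 5012 ± 297 FPKM. The glutathione genes gcs1 and pgr1 rose by 0.87 and 0.49, calls lost after rescaling. The manganese superoxide dismutase gene sod2 fell by 0.87 ± 0.12. When labelled deletion replicate 1 was left out the call of obr1 was kept, and without replicate 2 those of obr1 and srx1. In the core environmental stress list 3 of 16 rose (3 adjusted over the list alone; camera, adjusted p = 0.978), srx1, the phosphatase gene pyp2 (1.63) and pcr1 (0.44), whose call was lost after rescaling. The calls of pyp2 and pcr1 were lost when either labelled deletion library was left out, and hsp9 was at 6888 ± 117 against 15241 ± 5281 FPKM and was not called. Of 16 heat shock chaperone genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera, adjusted p = 0.18). These were mge1 (0.45), hsp104 (0.39) and hsp16 (-1.11), and all 3 calls were lost after rescaling and when either labelled deletion library was left out.

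The lists of other metals and of sulfur did not pass as sets. Of 14 tested genes of iron acquisition and regulation, the siderophore synthesis gene sib2 rose by 1.52 ± 0.15 and shu1 fell by 2.79 ± 0.57 (1 and 1 adjusted over the list alone). The list's median was 0.03, and -0.08 after rescaling, its mean was -0.14 and its set test pointed lower (camera, adjusted p = 0.655). Of 7 copper genes the transporter gene ctr5 rose by 0.80 and the chaperone gene atx1 by 0.58 (2 adjusted over the list alone; camera, adjusted p = 0.252). In sulfur, cysteine and methionine metabolism 5 of 16 rose (met9 by 0.99, met17 by 0.89, met16 by 0.83, met6 by 0.68 and sam1 by 0.61) and the sulfate adenylyltransferase gene sua1 fell by 0.94 (9 and 1 adjusted over the list alone; camera, adjusted p = 0.252). The calls of atx1, met17, sam1 and sua1 were lost after rescaling. When labelled deletion replicate 1 was left out the fall of shu1 was the 1 call kept in these 3 lists, and without replicate 2 all of their calls were lost.

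Ribosomal protein genes were lower as a set. All 141 genes of the cytosolic ribosomal protein list were tested, and 8 of them were lower. Their median was -0.49, which is -0.62 relative to the median of all tested genes. Members were taken by symbol, which brought in rpp1, rpp21 and rpp40, and these may not encode ribosomal proteins. With quantile normalization the median was -0.18, or -0.16 relative to that of all tested genes. The set was lower (camera, adjusted p = 2.42e-30), with an adjusted p = 0.622 with an estimated correlation, and it stayed lower after rescaling and with quantile normalization. Among the lower genes rps1801 fell by 0.74 ± 0.14, rpp203, fully overlapped, fell by 0.71, rps2202 fell by 0.71 and rpp101 fell by 0.62. In each of these wild-type replicate 2 lay above replicate 1, for rpp203 at 1121 against 904 FPKM. By limma 0 were called higher, and 0 in either direction adjusted over the list alone, against 98 lower and 0 higher at an unadjusted p under 0.05 and 7 lower and 0 higher with voom. After rescaling 5 of the 8 calls were kept, with quantile normalization 1, and all 8 were lost when either labelled deletion library was left out. Of 24 ribosome biogenesis genes 4 were higher (5 adjusted over the list alone; camera, adjusted p = 0.18), dbp2 by 0.81, erb1 by 0.59, mak16 by 0.50 and gar1 by 0.47. After rescaling the call of dbp2 was kept, and all 4 were lost when either labelled deletion library was left out.

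Respiratory genes were lower as sets without a called member. The 27 tested nuclear genes of the respiratory chain had a median of -0.16 (camera, adjusted p = 0.000271, and adjusted p = 0.556 with an estimated correlation), with rip1, fully overlapped, at 342 ± 10.9 against 474 ± 43.9 FPKM and cox13 at 606 ± 3.45 against 800 ± 4.04 FPKM. By limma 0 of them were called, also adjusted over the list alone, against 5 lower at an unadjusted p under 0.05 and 1 lower with voom, and 1 was lower after rescaling. The 8 tested mitochondrially encoded genes had a median of -0.75 (camera, adjusted p = 0.0147, and adjusted p = 0.656 with an estimated correlation), and this set did not pass after rescaling or with fry, though it did, as lower, with quantile normalization and with the replicate block. By limma 0 of these 8 were called, also adjusted over the list alone, against 2 lower at an unadjusted p under 0.05 and 0 with voom. With a library left out, SPMIT.01, SPMIT.06 and SPMIT.11 ran from -1.11 to -0.35, -1.15 to -0.39 and -1.33 to -0.29. In each of them labelled deletion replicate 2 was lowest and wild-type replicate 2 highest, as in the ribosomal RNA share given below. Of 10 core histone genes 0 were called by limma, also adjusted over the list alone, against 2 higher at an unadjusted p under 0.05 and 0 with voom (camera, adjusted p = 0.655, though the set passed as higher with quantile normalization).

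Among repeated gene families the Tf2 set was higher, and the wtf set did not pass, though it did, as higher, with the replicate block. The 13 near-identical Tf2 retrotransposons had a median of 0.36, which is 0.23 relative to the median of all tested genes. Of them Tf2-7 was called over all genes (0.63) and 13 were higher adjusted over the list alone, and the set was higher (camera, adjusted p = 0.00509, and adjusted p = 0.622 with an estimated correlation). The call of Tf2-7 was lost after rescaling and when either labelled deletion library was left out, and reads of these elements cannot be assigned to single copies. Of 25 wtf genes 3 rose, wtf2 by 2.53, wtf5 by 2.20 and wtf11 by 1.25 (3 adjusted over the list alone; camera, adjusted p = 0.14). Sequence found elsewhere too makes up 51.3% of wtf2, other transcripts cover 61.8% of wtf11, and the 3 calls were lost when either labelled deletion library was left out.

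**Figure D4:**
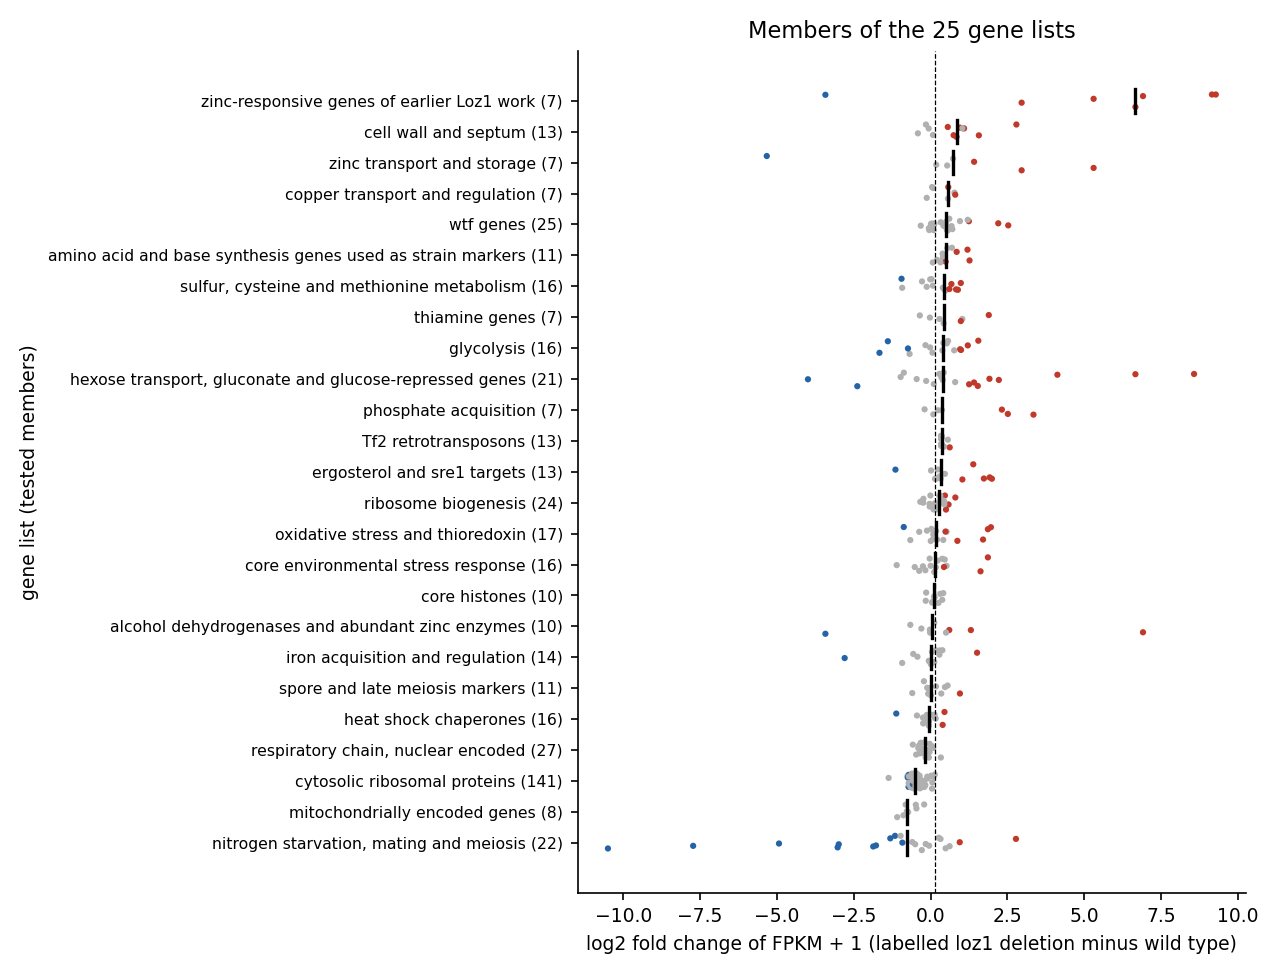
Log2 fold change of FPKM + 1 (labelled loz1 deletion minus wild type, horizontal axis) of the tested members of the 25 gene lists, 1 point per gene, red for called higher, blue for called lower and grey for not called, with a black bar at each list's median and a dashed line at the median of all tested genes. The zinc-responsive list has its median at 6.67, the mating list at -0.75 and the ribosomal protein list at -0.49.

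The share of each RNA class in summed FPKM was compared between the groups. With 2 against 2 the smallest possible p is 0.333, so this test could not pass for any class. Protein-coding genes held 84.2% ± 3.32 of summed FPKM in the labelled deletion libraries and 80.9% ± 2.53 in wild type (SD, n = 2, exact permutation test, two-sided, p = 0.667). Ribosomal RNA genes held 8.69% ± 3.62 and 12.3% ± 2.40 (exact permutation p = 0.667), with 11.3% and 6.13% in the labelled deletion libraries and 10.7% and 14.1% in wild type. The shares of non-coding RNA genes, 4.36% ± 0.0186 and 4.16% ± 0.0968, and of pseudogenes, 0.0434% ± 0.00154 and 0.0383% ± 0.00505, were higher in both labelled deletion libraries than in both wild-type libraries (exact permutation p = 0.333 for each). Without ribosomal RNA in the total the mean shares were 4.78% and 4.75% for non-coding RNA genes and 0.0475% and 0.0437% for pseudogenes.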

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

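None of the 100 named genes that were called reversed its direction under any alternative. Leaving out a library cannot reverse a gene whose groups do not overlap, so this was largely fixed in advance. How many calls stay in these fits depends on which pair gives the spread, and the wild-type pair differed more. The counts that follow therefore do not measure how far a call rests on 1 library. Of the 100, 49 or 45 stayed called when labelled deletion replicate 1 or 2 was left out, and all 100 did when either wild-type library was left out. The counts of higher and lower genes ran from 73 to 2115 and from 40 to 880 over the 4 fits that leave out a library. With no filter on mean FPKM, where more genes were tested, the counts were 491 and 161. With median-ratio rescaling 428 genes were higher, with quantile normalization 410, and with a replicate block and rescaling together 245. The fold rule without a test gave 337 higher genes, and calls that also need a 2-fold change were 269 and 150 by construction. The other planned settings stayed within 1.5 times of the counts. Of the tests chosen only after the data were seen, the fit without overlapping genes called 130 lower genes, on fewer genes tested, while its higher genes, voom and the fit without shared sequence stayed within 1.5 times. The odds ratio of the Loz1 motif near higher genes, 2.29, ran from 1.27 to 10.8 with a library left out, also chosen after the data were seen, and did not pass without wild-type replicate 1 or 2. Where no cause is named here, the cause was not tested.

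Same-numbered libraries did not deviate together (correlation across genes -0.01), so the replicate numbers were not taken as pairs. With the replicate block 538 genes were higher and 224 lower, and 10 lists passed as sets, the wtf and ergosterol lists among them.

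As sets, 8 of the 25 lists passed with camera, and 10 at an unadjusted p under 0.05. With an estimated correlation 0 passed, and 1 at an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 12 passed, without the ribosomal protein and mitochondrially encoded lists and with the sulfur, oxidative stress, phosphate, thiamine, spore and ergosterol lists, and after rescaling 9. With quantile normalization, chosen for the sets after the data were seen, 13 passed. The spore and late meiosis markers, which pointed lower with camera, pointed higher with fry (adjusted p = 0.0282, and 0.645 to 0.983 under the other alternatives) and with camera after rescaling (0.962). Camera's direction is relative to other genes and fry's to no change, so the directions are not alike in meaning, and the cause was not tested. The difference in the protein-coding share was 3.35 percentage points and -0.02 without ribosomal RNA in the total. Depth is known only as an estimate, so values near 0 FPKM were not read as absence.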

Other observations

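The genes in the first 2 paragraphs, SPMTR.02 and the tests of this part, except those of the Loz1 motif at 1000 and 500 bp in higher genes with all 4 libraries, were chosen only after the results were seen. Some genes around adh4 were higher too. Of 16 other protein-coding genes tested within 15 kb of adh4, 7 were higher, or 43.8% against 13.0% elsewhere (Fisher's exact test, two-sided, p = 0.0025, with genes not independent). These were the NADPH dehydrogenase gene SPAC5H10.10 (3.44), SPAC5H10.07 (2.44), SPAC5H10.03 (1.81), gmh1 (1.45), ecm31 (1.34), SPAC5H10.05c (1.22) and pan6 (0.76), and the others, from SPAC5H10.04 (-0.44) to otg1 (0.64), were not called. When either labelled deletion library was left out, SPAC5H10.10 and SPAC5H10.07 stayed called. None of the 16 had the Loz1 motif within 1000 bp upstream. The 16 lie between 50 and 200 kb from the end of chromosome I. Among all 320 protein-coding genes tested at that distance from a chromosome end, the 16 included, 61 were higher (19.1%). The 16 were not tested against this share. Other transcripts cover 93.9% of SPAC5H10.10, 88.8% of ecm31 and 97.3% of SPAC5H10.05c.

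Further genes outside the lists also changed. The biotin transporter gene vht1 was at 696 ± 41.6 FPKM in the labelled deletion libraries and 147 ± 19.0 FPKM in wild type (mean ± SD, n = 2), a rise of 2.24, the biotin synthase gene bio2 rose by 1.24 and the pantothenate transporter gene liz1, fully overlapped, by 1.71. SPAC1F12.10c, annotated as an NADPH-hemoprotein reductase, rose by 2.18. SPAC11D3.01c, of the Con-6 family, fell by 3.50, from 23354 ± 6449 to 2042 ± 339 FPKM, and SPAC869.09, of the same family and 83.8% overlapped, fell by 3.08. The iron-sulfur cluster assembly gene isu1 fell by 1.66, and the eisosome gene pil2 fell by 2.81. When either labelled deletion library was left out the calls of vht1, SPAC1F12.10c and SPAC869.09 were kept and those of bio2, liz1, SPAC11D3.01c, isu1 and pil2 were lost.

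The published Loz1 response element CGNMGATCNTY was more frequent upstream of higher genes when all 4 libraries were used. Within 1000 bp, 15 of 655 higher protein-coding genes had it (2.29%) against 44 of 4343 others (1.01%), an odds ratio of 2.29 (95% interval 1.18 to 4.22, Fisher's exact test, two-sided, p = 0.00993, genes not independent). Within 500 bp the odds ratio was 3.35 (Fisher's exact test, two-sided, p = 0.00356). The result at 1000 bp depends on which genes are called. When wild-type replicate 1 or 2 was left out it was 28 of 1865 or 19 of 1363 higher genes, with odds ratios of 1.53 and 1.27 that did not pass (Fisher's exact p = 0.106 and 0.381). With labelled deletion replicate 1 or 2 left out it was 6 of 61 or 6 of 57, with odds ratios of 10 and 10.8, and after rescaling 11 of 361 (3.0). With all 4 libraries it was 7 of 72 among genes at least 4-fold higher, and 1 of 172 among lower genes. The 15 genes included loz1, zrt1, mug15, its8, SPAC683.03, SPAC1F12.10c and tpx1. The targeted gene loz1 and zrt1, a zinc-responsive gene of earlier work, are also among the 7. The sources used here do not say which genes the published element was derived from, so the enrichment may be partly circular.

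By the ratio of mean FPKM, without the added 1, the loz1 transcript was 8.86 times as abundant in the libraries labelled as its deletion. An exchange of the labels between the groups would put the zinc-repressed genes of earlier work lower there, but their median, without loz1 and adh1, was 6.92 (5 genes, all higher), taking as background that Loz1 represses them. Wild-type RNA mixed into these libraries cannot by itself lift loz1 above the wild-type level, which the 8.86-fold ratio exceeds. This follows from the ratio alone and does not exclude that some wild-type RNA was present. Reads from parts outside the coding sequence left in place by the deletion, which make up 50.3% of the transcript, may account for a signal being present. At an unchanged level of the transcript they would give no more than the wild-type value, so alone they do not account for the 8.86-fold ratio. The files give 1 value per transcript, so where the reads lie stays open. A higher activity of the loz1 promoter, which has a motif match upstream, is a biological explanation that was not tested.

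Among the called mating genes those specific to M cells (mfm1, mfm2, mfm3, mam1 and mam2) fell, those specific to P cells (map2 and map3) rose and others fell, and the calls of map3 and mam2 were lost when either labelled deletion library was left out, that of map3 after rescaling too. Strains of different mating type may underlie this, since the M-specific cassette genes mat1-Mc and mat3-Mc, at 159 to 264 FPKM in wild type, were at 0.15 FPKM at most in the labelled deletion libraries. SPMTR.01 and SPMTR.02 were higher there whichever library was left out, SPMTR.02 at 12.3 and 8.48 FPKM and listed at 0 in both wild-type libraries. The named falls SPBC23G7.10c and SPNCRNA.388 lie between mat1-Mc and mat3-Mc and share no sequence with other loci. In wild type they were at 128 and 131 FPKM and at 21.1 and 26.0 FPKM. In the labelled deletion libraries they were at 1.22 and 1.06 FPKM and at 0 and 0.073 FPKM. Other genes of this stretch were not counted. As the cassettes split with genotype in all 4 libraries, a difference in mating type cannot be told apart from an effect of loz1 on the mating genes, which was not tested. A weaker mating programme in the labelled deletion strain stays open for the falls, since 5 of the 15 other tested members of the list were called lower (ste6, rgs1, spk1, ste11 and mei2, of which ste6 alone stayed called when either labelled deletion library was left out) and 0 higher. Called or not, 11 of the 15 lay below 0 and 4 above it, with a median of -0.50.

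Many genes near the ends of chromosomes I and II were called higher, most of them genes that share sequence with other loci. Of 48 protein-coding genes tested within 50 kb of these ends 34 were higher and 2 lower, with a median of 2.27, against 559 of 4609 genes at least 200 kb away, with a median of 0.14, and when labelled deletion replicate 1 or 2 was left out these counts were 19 and 33 or 19 and 28, and without wild-type replicate 1 or 2 they were 41 and 1670 or 36 and 1222. Within 50 kb of the ends of chromosome III 1 of 21 genes was higher and 2 were lower, with a median of -0.35. Scaling of the libraries does not account for this, since the median after rescaling was 2.16. Reads shared between copies may spread the rise of a few loci over many. Of 41 genes that share at least 10% of their sequence 31 were higher, with a median of 2.36. Of 7 genes of unique sequence 3 were higher and 2 lower, with a median of -0.46. With so few unique genes this cannot be told apart from a rise of the whole region (Fisher's exact test, two-sided, p = 0.171). That test counts genes that may share reads as independent. An effect of the genotype on these regions stays open as untested.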
